A study of Homo sapiens with 4 samples.

How the data were processed

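VDR was immunoprecipitated from PMA-differentiated THP-1 cells in 3 libraries (unstimulated, 1 h and 2 h of 1,25D), and 1 input DNA library was made, per the labels. Bowtie 1.0, MACS2 and SAMtools and the build hg19 are named in the submitters' processing notes; the MACS2 version and the significance threshold are not given in the sources used here. The deposited files hold, for each of the 3 VDR libraries, a list of peaks and a list of their summits, called on that library alone against input, as the deposited file names record. Replicates were not pooled, since each group had 1 library. The input library entered only through that peak calling.

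The score in the deposited lists was taken as the −log10 of a p or q value that the authors' peak caller gives each peak; the sources used here do not say which. It was the same in the peak and the summit list of each library. Such a score depends on read depth as well as on enrichment, and read depth is unknown here, so scores were ranked within a list and their sizes were not compared between lists. The exceptions are an alternative that puts a common minimum on all lists, and a rank correlation that describes the order of shared sites. Coordinates in the deposited lists count from 0 at the start and are printed here counted from 1, on hg19. Peaks were numbered without a gap in each list, every summit lay inside its peak, and no peaks of the same list overlapped.

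Samples were grouped by the treatment and treatment time in the labels. Peaks of different lists that overlapped by at least 1 bp were joined into sites with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3), and the number of sites was checked against bedtools 2.31.1. Sites were counted in each of the 7 combinations of the lists. Shares carry Wilson 95% intervals from scipy 1.17.1, which cover counting error only, and where a count of 0 is said to allow a share, that limit is 3 counts. Chance overlap was described by placing the peaks of a list at random within their chromosomes 1000 times. Each chromosome was taken to end at the last peak of any list, which makes it shorter than it is and chance overlap larger. Ranks of the unstimulated sites were set beside 10000 random draws of as many peaks from the same list. Figures were drawn with matplotlib 3.10.9. The overlap code was tested on 20 simulated pairs of lists with the sizes of the 1 h and 2 h lists and 100 planted shared peaks each; it recovered 100% of them, found 0 false ones, and matched bedtools in 20 of 20. Planted pairs were built to overlap and all other peaks lay far apart. The test therefore checks the code only, and not closely spaced peaks.

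With 1 library per condition no test across libraries was possible and no p-value was computed. The named sites follow a rule fixed before the data were examined: the 5 highest peaks of each list, the 5 highest by 2 h score of the sites in all 3 lists and of the sites at 1 h and 2 h only, and the 5 highest of the sites in a single list. This gave 21 sites. Alternatives fixed in advance were a minimum score equal to the median of the 2 h list, a reciprocal overlap of 50%, summits within 100 bp, and joining across gaps of up to 500 bp.

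The plan also held a search for the VDR element and other motifs at summits, the position of summits against genes, 16 gene lists to be counted near peaks, and a filter on repeat-masked sequence. These need the sequence or annotation of hg19. The gene table at hand was of another build (GRCh38), coordinates of different builds were not mixed, and so these parts were not analysed here.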

Results

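Genomic binding of the vitamin D receptor (VDR), the nuclear receptor for the active vitamin D hormone 1,25D, was profiled by chromatin immunoprecipitation and sequencing in THP-1 cells. THP-1 is a human monocytic leukaemia cell line. The cells had been turned into macrophages of an M2-like type with the phorbol ester PMA at 20 nM for 3 days. One VDR library came from unstimulated cells, 1 from cells given 100 nM 1,25D for 1 h and 1 from cells given the same dose for 2 h. A sample of input DNA served the authors' peak calling. Each condition had 1 library, so there was no replicate error, no p-value was computed, and each difference below is one between these libraries. The processed files were lists of peaks on the human genome build hg19 with a score per peak but no read counts, so the sequencing depth of each library was unknown. The score is the authors' own, the −log10 of a p or q value, and it was used to order peaks within a list. The exceptions were a common minimum score put on all lists and a rank correlation between 1 h and 2 h scores. Sites are named by position, since no gene annotation or sequence of hg19 was used here.

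Without ligand, VDR was called at 11 sites on 9 chromosomes. The highest score, 51.4, was on chromosome 3 (the peak spanned 48264123 to 48264644), followed by 42.5 on chromosome 19 (18613376 to 18613741) and 36.9 on chromosome 22 (32615116 to 32615464). A peak on chromosome 8 (61816721 to 61817017) had a score of 30.2, and the fifth, also on chromosome 8 (129960976 to 129961219), had 13.8. The lowest score of the list, 4.16, belonged to a peak on chromosome 12 (26451686 to 26451898). The 11 peaks covered 3.00 kb, with a median width of 244 bp and a median score of 12.1.

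The comparison of ligand with no ligand asks where VDR is found once the hormone is present. After 1 h of 1,25D, VDR was called at 143 sites on 22 chromosomes, 13 times as many as without ligand, covering 46.0 kb. All 11 sites of the unstimulated list were called again, and 132 sites were called at 1 h that were not called without ligand. The highest 1 h score, 176, was at the chromosome 8 site spanning 61816642 to 61817152 in this list. The next were the sites on chromosome 22 (32615043 to 32615505), with a score of 142, on chromosome 1 (119384078 to 119384487), with 125, on chromosome 3 (48264117 to 48264840), with 124, and on chromosome 19 (18613356 to 18613847), with 120. Of these 5, the chromosome 1 site alone had no peak in the unstimulated list. Peaks at 1 h had a median width of 304 bp and a median score of 15.8, with a range of scores from 2.59 to 176.

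After 2 h of 1,25D, VDR was called at 183 sites on 23 chromosomes, 16.6 times as many as without ligand, covering 61.7 kb. The 11 unstimulated sites were again all among them, and 172 sites were not called without ligand. The same 5 sites headed the list as at 1 h, in another order. The chromosome 3 site came first with a score of 161, then chromosome 22 with 153, chromosome 8 with 151, chromosome 19 with 132 and chromosome 1 with 126. Scores ranged from 2.61 to 161 around a median of 16.8, and the median width was 321 bp. The smallest width also differed between lists (182 bp without ligand, 217 bp at 1 h and 236 bp at 2 h), so widths and covered lengths are given for each list alone. With 11 of 11 unstimulated peaks found in each ligand list, the share not found again was 0, and a count of 0 among 11 allows up to 27.3%. When unstimulated peaks were placed at random within their chromosomes 1000 times, none overlapped a 1 h or 2 h peak. Peaks that cover so little of the genome rarely overlap at random, whatever gave rise to them. All 3 lists were called against input, of which the series lists 1 sample, so part of the sharing may come from that common reference. Under a reciprocal overlap of 50%, 8 of the 11 unstimulated peaks kept a partner in each ligand list.

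**Figure D1:**
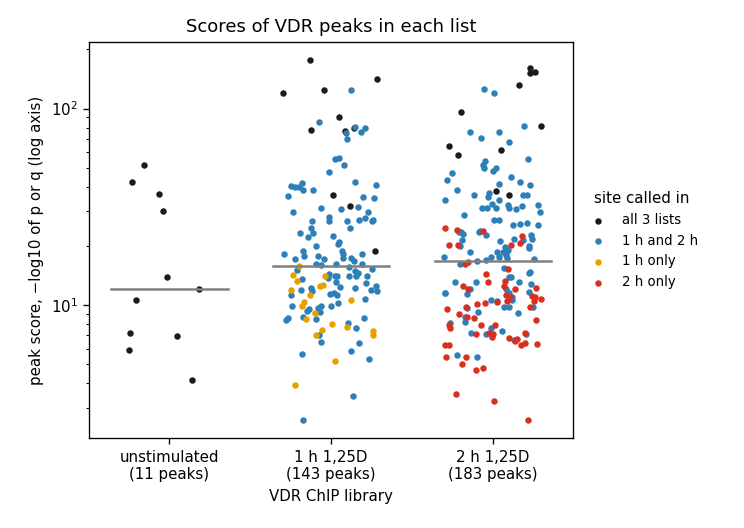
Peak score (−log10 of p or q as the authors' caller gave it, log axis) of each VDR peak in the 3 libraries, with each point 1 peak, colours for the lists that called the site and grey lines for the median of each list. The 11 unstimulated peaks reach 51.4 and belong to sites called in all 3 lists, the 1 h only sites stay at or below 15.8 and the 2 h only sites stay below 24.6; scores of different libraries are not on a common scale.

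Joined over the 3 lists, peaks that overlapped by at least 1 bp formed 204 sites. Of these, 193 sites, or 94.6% (Wilson 95% interval 90.6 to 97.0%), were called only after ligand. This share largely restates the list lengths, 11 peaks without ligand against 143 and 183 after it. The largest class was the 111 sites called at both 1 h and 2 h but not without ligand, 54.4% of all sites (47.6 to 61.1%). Sites called at 2 h only numbered 61, or 29.9% (24.0 to 36.5%). Sites called at 1 h only numbered 21, or 10.3% (6.83 to 15.2%), and the 11 sites called in all 3 lists made up 5.39% (3.04 to 9.40%). No site was called without ligand only, or without ligand and in just 1 of the ligand lists. Only the 11 unstimulated peaks could fall in these 3 classes, and a count of 0 among 11 allows up to 27.3% of them. The intervals of the shares cover counting error only. The 2 h list is the longer one. In an alternative chosen after the data were seen, it was limited to the length of the 1 h list. This gave 32 sites at 2 h only and 32 at 1 h only, equal by construction. With a minimum score of 16.8 in every list, 30 sites passed at 2 h only and 4 at 1 h only. These were largely other sites than the 61 and 21. None of the 21 passed, since their highest score was 15.8, and 8 of the 61 did. The others were called in both ligand lists, with 1 score under the minimum. Scores of different libraries are not on a common scale.

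The sites called at both times after ligand, and not before, were headed in the 2 h list by the chromosome 1 site already named (119384054 to 119384487). It was followed by a site on chromosome 15 (65175303 to 65175725), with scores of 85.2 at 1 h and 119 at 2 h. A site on chromosome 20 (23314526 to 23315408) was the widest of the 204 at 883 bp, and scored 76.4 at 1 h and 81.9 at 2 h. Sites on chromosome 19 (17220783 to 17221187) and chromosome 2 (9400687 to 9401326) had 2 h scores of 76.4 and 76.1.

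**Figure D2:**
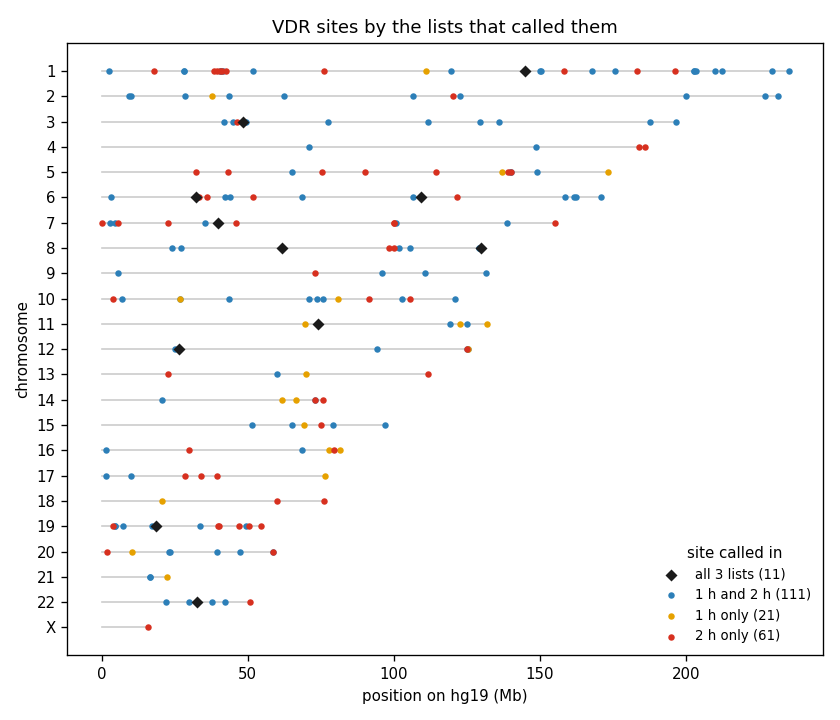
Position on hg19 (horizontal axis, Mb) of the 204 VDR sites on each chromosome (vertical axis), with colours for the lists that called each site, diamonds for the 11 sites of all 3 lists and grey lines up to the last site of the chromosome. Chromosome 1 carried 31 sites and chromosome X carried 1.

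The sites of the unstimulated list lay near the top of both ligand lists. In the 2 h list their median rank by score was 8 of 183, and the last of them ranked 32. Among 10000 random draws of 11 peaks from that list, 0 had a median rank as low, and the mean of the draws' medians was 92.1. In the 1 h list their median rank was 9 of 143 and the last ranked 57. In 10000 draws from this list, 1 had a median rank as low. The draws were added after the results were seen and only describe the ranks. They treat weak and strong peaks as equally likely to be called without ligand. The order was not carried over exactly. The chromosome 12 site with the lowest unstimulated score (26451566 to 26452045) ranked 11 in the 1 h list and 7 in the 2 h list. The chromosome 1 and chromosome 15 sites that ranked 5 and 6 in the 2 h list were not called without ligand. Ranks in lists of different length do not measure a change in binding.

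The comparison of 2 h with 1 h asks whether the set of VDR sites changes with the time under ligand. Of the 143 peaks at 1 h, 122 were called again at 2 h, or 85.3% (Wilson 95% interval 78.6 to 90.2%), while random placement gave a mean of 0.008 and at most 1. Lists that cover so little of the genome rarely overlap at random. The placement therefore does not separate VDR binding from other sources of shared peaks. The same 122 made up 66.7% of the 2 h peaks (59.6 to 73.1%). The 2 h list held 1.28 times as many peaks as the 1 h list. Restricted to its 143 highest peaks, the 2 h list shared 111 with the 1 h list, a choice made after the data were seen. Across the 122 shared sites, Spearman's rho between 1 h and 2 h scores was 0.81, as a description of their order across sites, which are not independent replicates.

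Sites called at 1 h only had low scores within their list. The highest was 15.8 on chromosome 10 (26776554 to 26776808), followed by 14.2 on chromosome 1 (110880928 to 110881201), 14.05 on chromosome 2 (37843558 to 37843862), 13.2 on chromosome 14 (66606926 to 66607210) and 12.6 on chromosome 21 (22423477 to 22423711). The first of these ranked 72 of 143, and 0 of the 21 lay above the median score of the 1 h list. The sites called at 2 h only reached further up within their own list, which is the longer one. Their highest score was 24.5 on chromosome 16 (30066258 to 30066604), then 24.1 on chromosome 1 (158119453 to 158119716), 23.7 on chromosome 18 (75929431 to 75929826), 22.5 on chromosome 17 (39636492 to 39636830) and 20.7 on chromosome 6 (33398275 to 33398586). The first of these ranked 56 of 183, and 8 of the 61 lay above the median of the 2 h list, or 13.1% (6.80 to 23.8%). This difference depends on list length. A chromosome 3 site (135794728 to 135795089) ranked 56 at 1 h and 155 at 2 h. With the 2 h list limited to 143 peaks it would count as 1 h only.

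The share of peaks called at both times after ligand was 100% in the highest-scoring part of each ligand list and lower in its lowest part, with Wilson intervals that did not overlap. With each list cut into 4 parts of nearly equal size by score, all 36 peaks of the highest part at 1 h were called at 2 h, and all 46 of the highest part at 2 h were called at 1 h. A count of 0 missing allows up to 8.33% and 6.52% of these parts. In the lowest part, 23 of 36 peaks at 1 h (63.9%, 47.6 to 77.5%) were called at 2 h, and 15 of 46 peaks at 2 h (32.6%, 20.9 to 47.0%) were called at 1 h.

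**Figure D3:**
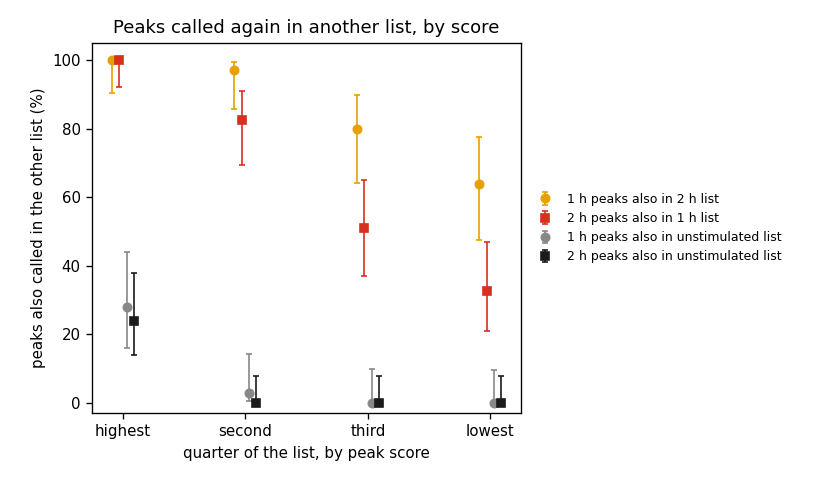
Percent of peaks in a list that were also called in another list (vertical axis), for 4 parts of each list from the highest to the lowest scores (horizontal axis), with points for the share and bars for Wilson 95% intervals. Sharing between 1 h and 2 h runs from 100% in the highest part to 63.9% and 32.6% in the lowest, and all 11 unstimulated sites fall in the highest part of the 2 h list.

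Distances between summits were measured within sites, where the overlap of the peaks already limits them. Between 1 h and 2 h, the median distance over 122 sites was 27.5 bp (quartiles 14 and 47 bp), and 95 sites (77.9%) had summits within 50 bp of each other. The distance exceeded 100 bp at 9 sites, the largest being 187 bp on chromosome 5 (149060634 to 149061007). Between the unstimulated and the 1 h library the median distance was 18 bp, and between the unstimulated and the 2 h library 38 bp, over 11 sites each. In a split chosen after the data were seen, the median distance between 1 h and 2 h was 21 bp for the 61 sites with the highest 2 h ranks and 37 bp for the other 61 (upper quartile 67 bp). The signed shift from 1 h to 2 h had a median of 0.5 bp.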

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

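With a minimum score of 16.8, the median of the 2 h list, 4 unstimulated, 66 peaks at 1 h and 92 at 2 h remained, so that ligand lists were 16.5 and 23.0 times as long as the unstimulated one. All 4 unstimulated peaks still had partners in both ligand lists, 62 of the 66 at 1 h were shared with 2 h, and the sites then numbered 4 in all lists, 58 at 1 h and 2 h, 4 at 1 h only and 30 at 2 h only. The fall in these counts follows from the filter itself. It also moved sites between classes, since none of the 21 sites at 1 h only passed and 8 of the 61 at 2 h only did. The 4 at 1 h only and the rest of the 30 at 2 h only were shared sites whose other peak fell under the minimum. Among sites with both scores over that minimum the median summit distance between 1 h and 2 h was 20.5 bp, an alternative chosen after the data were seen; the 61 shared sites lowest by 2 h rank had 37 bp. A reciprocal overlap of 50% left 3 sites in the unstimulated list only, because the unstimulated peaks there were less than 50% as wide as the ligand peaks that contained them; one is the chromosome 12 site named in the results. With the 2 h list limited to the length of the 1 h list, also chosen afterwards, 32 sites were in each single list, equal by construction. Requiring summits within 100 bp or joining gaps of up to 500 bp left every count of overlaps and classes within 1.5 times its main value. No direction reversed. The summit list carries the same scores as the peak list, so the planned ranking by summit height was no alternative, and the repeat filter and the motif and gene settings were not run without hg19 sequence. No paired analysis was possible because each group has 1 library. Read depth is unknown, which limits the comparison of list lengths.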

Other observations

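More pairs of neighbouring VDR sites lay within 50 kb and within 100 kb than in any random placement. In 9 places, neighbouring sites lay within 50 kb of each other, while random placement of the 204 sites within their chromosomes gave a mean of 0.865 such pairs and at most 5 in 1000 placements. With limits of 20 kb and 100 kb there were 4 and 13 pairs, against random means of 0.326 and 1.77 and random maxima of 4 and 8, so that at 20 kb a random placement reached the observed count. The closest pair, 475 bp apart, was on chromosome 20, where a site called at 2 h only (58629834 to 58630178) adjoined a site called at both times (58630654 to 58631007). The planned joining of gaps of up to 500 bp makes this pair 1 site called at both times. Another pair, 1.12 kb apart, was on chromosome 19 (4562141 to 4562461 and 4563582 to 4563916), both called at 1 h and 2 h. On chromosome 5, a site called at both times (139986620 to 139986964) lay 25.7 kb from one called at 2 h only (140012648 to 140013070). The densest stretch of 5 Mb was on chromosome 1, with 8 sites between 38326145 and 42628281, 5 of them called at 2 h only. Random placement gave at most 7 sites in any such stretch in 1000 placements. The 5 sites at 2 h only ranked from 122 to 177 of 183 in the 2 h list. The excess over 7 therefore rests on low-scoring calls of 1 library. Random placement takes no account of genes or open chromatin. The tests of neighbouring sites, of the densest stretch, of ranks, of scores of sites in a single list and of shared smallest widths, the use of summit distances against an artefact, and the sites named in this paragraph were chosen after the results were seen.

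Every site called without ligand was also called after ligand, and these sites lay high in the ligand lists. Of these 11 sites, 6 were among the 11 highest peaks at 2 h and 7 among the 11 highest at 1 h, where random draws gave means of 0.642 and 0.848 and at most 4 and 6. Their high ranks restate the pattern, so whether fewer peaks pass the calling threshold before ligand and the strongest sites pass first stays open. The lists did not follow one strict order, since 21 peaks of the 2 h list ranked above the last of the 11 and were not called without ligand. An artefact of input or mapping cannot be told apart from binding at these sites, since a fixed artefact would also keep its place. The summits without ligand and at 2 h lay a median of 38 bp apart. This is within the upper quartile of 47 bp for 1 h against 2 h over all 122 shared sites. It is beyond the 30 bp of the 61 shared sites with the highest 2 h ranks, which include these 11. Between the unstimulated and the 1 h library the median was 18 bp, within both, so the distances do not decide. More VDR on chromatin under ligand, which the design names, stays open and untested, as does a difference in read depth.

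Sites called in only 1 of the ligand lists had low scores. Of the 82 such sites, 0 lay above the upper quartile of their own list, and a count of 0 allows up to 3.66%. This restates that sharing rose with score, so whether these are calls near the threshold stays open. Binding that begins after 1 h stays open as well: 8 of the 61 sites called at 2 h only lay above the median of their list, against 0 of the 21 called at 1 h only (intervals 6.80 to 23.8% and 0 to 15.5%). These intervals overlap, and a deeper 2 h library would give the same picture.

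The smallest width was 182 bp without ligand, 217 bp at 1 h and 236 bp at 2 h, and it was shared by 2, 9 and 9 peaks. The shared values are the pattern itself, so whether there was a minimum width set per library by the peak caller stays open.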
